A study of Homo sapiens with 12 samples.

How the data were processed

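RNA was measured in human CD34+ haematopoietic stem and progenitor cells from mobilized peripheral blood, which had been treated ex vivo for 4 h with vehicle, dexamethasone, 16,16-dimethyl prostaglandin E2 (dmPGE2) or both agents. There were 12 arrays of the Affymetrix Human Genome U133 Plus 2.0 type, 3 per group, and every array entered the comparisons. Per the labels' protocols, RNA was extracted with a PicoPure kit and amplified with a whole-transcript pico kit. The authors deposited 1 log2 value per probe set and array, and per the submitters' processing notes these were made with RMA and the Transcriptome Analysis Console, with no versions stated. The 54675 deposited values per array ran from 1.74 to 14.9, and the array medians lay between 6.05 and 6.25, so they were used as given with no further normalization. An array has no read depth, so the number of arrays limits the precision. The 27 probe sets for bacterial transcripts, which human RNA does not match, served as a background, and their 95th percentile over all arrays was 4.81.

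Gene symbols came from the platform's probe table, and its Entrez Gene identifiers were looked up in a RefSeq gene table of the GRCh38.p14 assembly, in which 54 identifiers had no match and 0 symbols needed updating. No coordinates are given, since the array files name no genome build. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. Only those with 1 symbol were used, and 59 probe sets for XIST, TSIX and Y-linked genes were left out of every test. The remaining 41038 probe sets measured 19740 genes. Where a gene had more than 1 probe set, as 10511 genes did, the probe set with the highest mean over all arrays stood for it. No filter was set on dim probe sets.

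The groups and the donor numbers 1 to 3 were taken from the sample titles. All 12 arrays were fitted in 1 linear model with a mean per group, using lmFit and eBayes of limma 3.58.1 in R 4.3.3. The p-values of each comparison were adjusted over all 19740 genes by the Benjamini-Hochberg method, and a gene passed at an adjusted p below 0.05. Every adjusted p for a single gene is from this two-sided limma test unless stated. The comparisons were each treatment against vehicle, the combination against each agent alone, dexamethasone against dmPGE2, and the interaction. The interaction asked whether the log2 effect of both agents together differed from the sum of their separate effects. Errors are standard errors (SE) of the fitted difference in this fit, which held no donor term, or standard deviations (SD) of a group of n = 3 arrays. The deposited values are on the log2 scale, so differences are log2 fold changes, and a fold is 2 to the power of the log2 difference.

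The titles give donors 1 to 3 in every group, so the numbers pair the arrays. The values showed the same pairing. After the group means were subtracted, the 18 pairs of arrays with 1 number had a median correlation of 0.752 and a lowest one of 0.591, the 36 pairs with different numbers had a median of -0.394, and 12 of 12 arrays correlated best with an array of their own number. The fit without a donor term had been fixed before the data were examined, and the fit with the donor number as a block had been fixed as its alternative. The blocked adjusted p is given beside the result of a named gene or list where it changed the call. No fold is given for a change from a mean under the percentile of the bacterial controls. The block lowered the median residual SD from 0.315 to 0.194.

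Before the data were examined, 21 gene lists were fixed. They were glucocorticoid receptor targets, cAMP and CREB targets, immunoregulatory molecules, inflammatory cytokines and NF-kB targets, type I interferon response, antigen presentation by MHC class II, haematopoietic stem cell genes, homing adhesion and migration, cell cycle, apoptosis and survival, cholesterol synthesis, ribosome biogenesis and MYC targets, prostaglandin and glucocorticoid signalling components, heat shock and handling stress, and markers of T and NK cells, B cells, monocytes and dendritic cells, granulocyte precursors, erythroid cells, megakaryocytes and platelets, and mast cells and basophils. Each list was compared with all other genes by camera of limma with a preset correlation between genes of 0.01, and adjusted over the 21 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move at all, were the alternatives. Members were also counted after the p-values had been adjusted over the list alone.

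The genes named in the text follow a rule fixed before the data were examined. Against vehicle it takes the 12 largest changes in each direction among genes that passed and had 1 sign in all 3 donor pairs, and for the other comparisons 6 in each direction. Where no gene passed it takes the 5 smallest p. It adds up to 6 members with the smallest p from each list, and all members of the list of prostaglandin and glucocorticoid signalling components may be named. The following were named outside the rule, after their values were seen. They were AKR1C1, AKR1C2, AKR1C3, FEZ1, HMOX1, LTB, MMP7, PNMT, SHISA2 and VMP1 for dexamethasone against vehicle, CXCL6, CXCL14, PDE2A, PDE4A and the GIMAP genes for dmPGE2 or the combination against vehicle, AKR1C1, AKR1C2, CRYBG1, IKZF1 and PDE2A for the combination against dmPGE2, and AKR1C2, CD274, CRYBG1, GIMAP8 and TRAF3IP3 for the interaction.

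Calls shared between comparisons were set beside the overlap of independent lists. For the pair of effects measured against the same vehicle arrays, unchanged groups were also simulated against those arrays 100 times, since 3 arrays cannot be split into parts of at least 2. The other settings tried were eBayes with a trend and robust prior, only genes above the 40th percentile of mean value, quantile normalization applied again, each array centred on its median, the mean over a gene's probe sets, only the arrays of the groups compared, a further threshold of an absolute log2 fold change of 1, and leaving out each array and each donor number in turn. None of these settings held the donor block, so leaving out 1 array also left its donor unmatched. The steps were tested on simulated data for dexamethasone against vehicle, in which known changes were added to the 19740 genes. The fit without the block recovered 19.4% of genes changed by 1 on the log2 scale, 83.6% of those changed by 2 and 97.0% of those changed by 3, with 0 false calls among the genes left unchanged. With the block it recovered 94.0%, 100% and 100%, with 18 false calls. A list shifted by 0.5 on the log2 scale was recovered by camera. Of the 20 other lists, which were not shifted, 1 was called falsely. Apart from the donor effects, the simulated noise was drawn separately for each gene. This test therefore does not show how camera treats lists whose genes vary together.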

Results

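The data are whole-transcriptome expression values of 12 arrays, 3 each for human mobilized CD34+ cells treated with vehicle (dimethyl sulfoxide), 10 µM dexamethasone, 10 µM dmPGE2 or both agents. CD34+ cells of mobilized blood are the stem and progenitor cells used for haematopoietic transplantation. Dexamethasone is a synthetic glucocorticoid, and dmPGE2 is a prostaglandin E2 analogue that resists degradation. The cells had been incubated for 4 h at 37 °C, and cells of donors 1 to 3 were present in every group. The values are log2 RMA signals per probe set, and 19740 genes were compared. The series title places the work in the use of pharmacologically enhanced stem cells in autoimmune diabetes, and the 4 groups ask how each agent and both together alter the cells' expression.

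Most of the variation followed the donor numbers and dmPGE2. Of the total variance between arrays, 55.8% lay between donor numbers, 31.5% between treatment groups and 12.7% in neither. The first principal component held 43.7% of the variance, and 86.2% of it lay between donor numbers. The second held 23.3%, and 92.1% of it separated the arrays with dmPGE2 from those without. The third held 16.8% and again followed the donor numbers. Since cells of each donor received all 4 treatments, results of the fit with a donor block are given beside those without it where the call of a named gene or list differed or a count of calls moved by over 1.5 times.

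**Figure D1:**
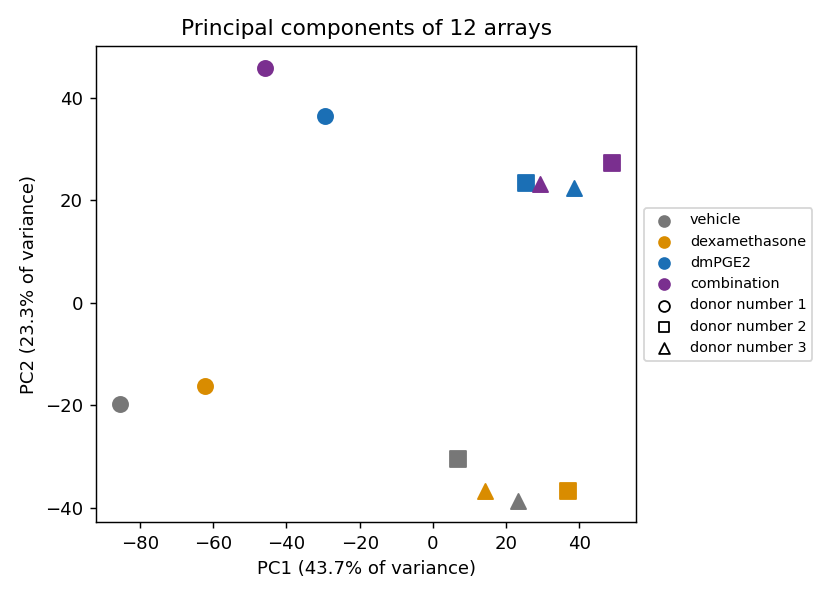
Scores of the 12 arrays on principal component 1 (43.7% of the variance) and principal component 2 (23.3%), with colours for the treatment groups and marker shapes for the donor numbers. The arrays with dmPGE2 lie apart from those without it along component 2, and donor 1 lies apart from donors 2 and 3 along component 1.

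The comparison of dexamethasone with vehicle asked what the glucocorticoid changed alone. CXCR4 (Entrez Gene 7852), the receptor for the chemokine CXCL12 that holds stem cells in the marrow, rose by 1.89 on the log2 scale (SE 0.17, 3.71-fold), from 10.82 ± 0.09 in vehicle to 12.72 ± 0.16 (SD, n = 3). FKBP5 (Entrez Gene 2289), a co-chaperone of the glucocorticoid receptor, rose by 1.85 (SE 0.18, 3.59-fold), from 12.18 ± 0.18 to 14.02 ± 0.13 (SD, n = 3). These were the only genes that passed without a donor block, with limma adjusted p = 0.00651 and 0.00777, and both were higher in 3 of 3 donor pairs. Their other probe sets were higher by 2.49 to 2.63 for CXCR4 and by 2.42 to 2.99 for FKBP5. With the donor block, 68 genes rose and 14 fell. An unadjusted p below 0.05 was found for 244 genes without the block and for 1315 with it. Without the block the donor differences stayed in the residual spread, so the 244 do not speak against changed genes. Among the genes that passed only with the block were TSC22D3, which encodes the glucocorticoid-induced leucine zipper (log2 fold change 2.81, blocked adjusted p = 0.000256), the transcription factor gene ZBTB16 (2.55, 0.000643), and FLT3, the receptor tyrosine kinase of progenitors (1.14, 0.0135). The kinase gene SIK1 (2.35, blocked adjusted p = 0.000193, with -0.06 in its other probe set), the cyclin gene CCND3 (1.25, 0.0015), the insulin signalling adaptor IRS2 (1.38, 0.0135) and GADD45A (1.05, 0.00705) were also called higher with the block. Called lower with the block were the matrix protease MMP9 (-0.99, blocked adjusted p = 0.00694), the interleukin-1 receptor antagonist IL1RN (-1.02, 0.0176) and the haem-degrading enzyme HMOX1 (-1.28, 0.00255). The largest blocked changes outside the lists were higher values of SHISA2 (3.25, blocked adjusted p = 0.00131, from a vehicle mean under background), the protease MMP7 (3.17, 0.000256) and the adrenaline-synthesizing enzyme PNMT (2.71, 0.000229), and lower values of LTB (-1.86, 0.0347, with -0.21 in its other probe set), FEZ1 (-1.63, 0.00321, with -0.34 in its other probe set) and VMP1 (-1.40, 0.0365). AKR1C1, AKR1C2 and AKR1C3, which encode steroid and prostaglandin reductases, were called higher with the block by 0.80 to 0.88 (blocked adjusted p = 0.0421, 0.0309 and 0.0365), and 2 of the 4 other probe sets of AKR1C1 were not higher.

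Glucocorticoid receptor targets rose as a group with dexamethasone. Of 27 measured members, 2 rose, 0 fell and 25 did not pass in limma, while 11 rose and 0 fell when adjusted over the list alone, and 11 rose with the donor block. The median log2 fold change was 0.81, and camera gave an adjusted p = 1.54e-28, or adjusted p = 0.000579 with an estimated correlation. The targets SMAP2 (1.28, blocked adjusted p = 0.00848) and FLT3 (1.14) were among the members called with the block. Inflammatory cytokines and NF-kB targets had a median of -0.45 and a camera adjusted p = 7.61e-08, with 0 of 26 members called and 0 adjusted over the list alone. With the block 0 members passed over all genes, but 8 fell and 1 rose when adjusted over the list alone. This list's adjusted p = 0.87 with an estimated correlation, or blocked adjusted p = 0.614. Its members with the smallest p were the adhesion molecule ICAM1 (-1.49), the signalling adaptor TRAF1 (-1.28) and the chemokine CXCL3 (-1.19). None of these passed over all genes with or without the block. Of 32 immunoregulatory molecules, 0 passed, and 2 were lower with the block. CD274, which encodes the checkpoint ligand PD-L1, was 1.20 higher on the log2 scale (SE 0.61, adjusted p = 1, blocked adjusted p = 0.258) and higher in 3 of 3 pairs. Its difference was 0.46 without vehicle replicate 3, which left donor 3 unmatched, and 0.61 without replicate 3 of all groups. The remaining 18 lists were not called, and in them the block called 2 cAMP and CREB targets, 1 homing, 1 cell cycle, 1 apoptosis and 1 megakaryocyte gene higher and 1 homing gene lower.

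In the fit without the block, both calls depended on single arrays. The blocked fit, which also called both genes, was not refitted with arrays left out. Without vehicle replicate 2, CXCR4 and FKBP5 had adjusted p = 0.0737 each, FKBP5 had adjusted p = 0.068 without dexamethasone replicate 1, and neither passed when any 1 donor number was left out, while the changes of CXCR4 stayed between 1.76 and 1.97. Of the genes called only with the block, the log2 difference moved by over 1.5 times when 1 array was left out for AKR1C1 (0.39 without dexamethasone replicate 1), AKR1C2 (0.51 without the same array), AKR1C3 (0.29 without vehicle replicate 3), IL1RN (-0.66 without vehicle replicate 2), HMOX1 (between -2.00 and -0.64) and VMP1 (between -2.41 and -0.52). These refits had no donor block, so leaving out 1 array left its donor unmatched, and they do not test the blocked calls. None of these genes moved by over 1.5 times when all arrays of 1 donor number were left out. Of the uncalled genes named above, CXCL3 went to -0.78 without dexamethasone replicate 3, ICAM1 to -2.31 without vehicle replicate 3 and TRAF1 to -0.74 without replicate 2 of all groups. The count of 2 genes became 0 without vehicle replicate 2, 5 without vehicle replicate 3, 1 without dexamethasone replicate 1 and 4 without dexamethasone replicate 2.

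The comparison of dmPGE2 with vehicle asked what the prostaglandin changed alone. In it 183 genes rose and 49 fell, or 1159 and 1252 with the donor block. TKTL1 (Entrez Gene 8277), which encodes a transketolase-like protein, rose by 7.40 on the log2 scale (SE 0.32, adjusted p = 2.25e-06), from 4.11 ± 0.43 in vehicle, under the background percentile of 4.81, to 11.51 ± 0.26 (SD, n = 3). CEMIP, a hyaluronan-binding protein, rose by 6.97 (SE 0.33, adjusted p = 3.29e-06), and its other probe set was 1.15 higher. The gap junction gene GJA1 (6.26), the chemokine CXCL5 (6.16), the protein kinase A anchor AKAP12 (5.85), the neuropeptide precursor TAC1 (5.59), SV2C (5.52), the phosphatase DUSP4 (5.32), THBS1 (4.99), the carbonic anhydrase CA2 (4.97), the thrombin receptor THBD (4.92) and tissue plasminogen activator PLAT (4.77) followed. Each was higher in 3 of 3 donor pairs. The vehicle means of TKTL1, CEMIP, GJA1, TAC1, SV2C and PLAT lay under the background percentile, as did the mean of NHSL2 with dmPGE2, so the size and rank of these changes are uncertain. Falls were smaller, and among the genes that passed without the block the largest were those of CHST13 (-2.49), the ARF exchange factor CYTH4 (-2.39, SE 0.43), the growth factor PDGFA (-2.26), UMODL1 (-2.23) and NHSL2 (-2.19). The pro-apoptotic BMF (-1.82), GLIS2 (-1.78), CEP126 (-1.61), the leukocyte integrin ITGAL (-1.59), TRAF3IP3 (-1.57), C2CD2 (-1.56) and the phosphatase PTPN6 (-1.55) fell as well. Other probe sets changed by much less for TKTL1 (2.41), CXCL5 (0.60 and 1.94), CHST13 (-0.19) and NHSL2 (-0.08).

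cAMP and CREB targets rose with dmPGE2, whose EP2 and EP4 receptors couple to adenylyl cyclase. Of 27 measured members, 10 rose, 0 fell and 17 did not pass, and 21 rose when adjusted over the list alone. The donor block called 23 higher and 0 lower. The median log2 fold change was 1.80 and the camera adjusted p = 2.16e-35, or adjusted p = 0.00623 with an estimated correlation. CREM, a cAMP-responsive transcription factor, rose by 4.00 (SE 0.42, 16.1-fold), the nuclear receptor NR4A3 by 3.65 (SE 0.31), SIK1 by 4.41 (SE 0.53, with -0.02 in its other probe set), and the cAMP-degrading phosphodiesterases PDE4B and PDE4D by 3.36 (SE 0.34) and 2.48 (SE 0.33). Glucocorticoid receptor targets were called with dmPGE2 too, with 5 risen, 0 fallen and 22 not passed, 6 risen and 2 fallen when adjusted over the list alone, and 9 higher and 4 lower with the block. Their camera adjusted p = 0.00156, but adjusted p = 0.152 with an estimated correlation. The members that rose were CXCR4 (2.42, SE 0.17, 5.36-fold, adjusted p = 5.72e-05), SGK1 (2.91), RGS2 (3.29), ERRFI1 (1.84) and DDIT4 (1.62). RGS2 also belongs to the cAMP list.

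Apoptosis and survival genes had 3 members risen, 0 fallen and 20 not passed, with 4 risen when adjusted over the list alone, and 5 higher and 1 lower with the block. The camera adjusted p = 0.0129, but adjusted p = 0.149 with an estimated correlation. The 3 were the anti-apoptotic MCL1 (1.12), the pro-apoptotic BCL2L11 (2.38) and the growth arrest gene GADD45A (1.26). Heat shock and handling stress genes had 0 of 18 called, 1 higher when adjusted over the list alone, 4 higher and 3 lower with the block, a median of 0.21 and a camera adjusted p = 0.0398, with adjusted p = 0.566 with an estimated correlation. SLC2A1 (1.88) and ADM (1.43), both known as hypoxia-responsive, were among the 4 that were higher with the block (blocked adjusted p = 3.26e-05 and 0.000541).

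The list of immunoregulatory molecules was not called with dmPGE2 (camera adjusted p = 0.353), with 2 members risen, 1 fallen and 29 not passed, 3 risen and 1 fallen when adjusted over the list alone, and 4 higher and 3 lower with the block. NT5E, the ectoenzyme CD73 that makes adenosine, rose by 3.19 (SE 0.66, adjusted p = 0.0479) from a vehicle mean of 4.79, under the background percentile, arginase ARG2 rose 2.83-fold (SE of log2 0.25, adjusted p = 0.0146), and the checkpoint molecule VSIR fell by 0.87 on the log2 scale (SE 0.17, adjusted p = 0.0413). Homing, adhesion and migration genes had 3 risen, 1 fallen and 24 not passed, with the same counts when adjusted over the list alone and a camera adjusted p = 0.795. With the block 4 were higher and 5 lower, so that the balance between rises and falls depended on the fit. Besides CXCR4, the sphingosine 1-phosphate receptor S1PR1 (3.05) and MMP9 (1.63) rose and ITGAL fell, the median was -0.13 and the mean 0.09. Of 26 inflammatory cytokines and NF-kB targets 0 passed, against 3 higher and 7 lower with the block. The interferon-induced chemokine CXCL10 was 3.53 lower on the log2 scale in that fit (log2 fold change -3.53, blocked adjusted p = 0.0024).

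Stem cell genes moved in both directions with dmPGE2. Of 25 measured members, 0 passed, 3 were higher and 3 lower when adjusted over the list alone, and 6 were higher and 4 lower with the block (camera adjusted p = 0.444). KIT, the stem cell factor receptor, was 1.76 higher (blocked adjusted p = 6.27e-05) and AVP 1.26 higher (0.000619), while the transcription factor genes GFI1B (-2.24, 5.34e-05) and LMO2 (-1.20, 0.000306) were lower. Of 26 components of prostaglandin and glucocorticoid signalling, 0 passed, 1 was higher when adjusted over the list alone, and 5 were higher and 4 lower with the block (camera adjusted p = 0.449). With the block, the glucocorticoid receptor gene NR3C1 was 0.89 higher (blocked adjusted p = 0.00544), the prostaglandin receptor genes PTGER3 and PTGER4 were 0.84 and 0.96 higher (0.0398 and 0.0335, PTGER4 in 2 of 3 pairs with 0.24 in its other probe set, and the 9 other probe sets of PTGER3 between -0.31 and 0.20), and PTGER2 was lower (log2 fold change -0.99, blocked adjusted p = 0.00259). ADCY9, an adenylyl cyclase (-0.94, 0.000594, with -0.26 and -0.06 in its other probe sets), and the prostaglandin D synthase HPGDS (-0.96, 0.00411) were also called lower with the block. In the dexamethasone group NR3C1 differed from vehicle by 0.08 (SE 0.20, adjusted p = 1).

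The count of genes called with dmPGE2 was 134 without vehicle replicate 1, 135, 124 and 142 without dmPGE2 replicates 1, 2 and 3, and 40 to 72 when all arrays of 1 donor number were left out. Of the 47 named genes called, 25 stayed called without any 1 array, and 10 also without any 1 donor number, among them TKTL1, CEMIP, CXCL5, AKAP12, THBD, PLAT and CXCR4. Of the genes called only with the block, ADCY9 went to -0.43 and HPGDS to -0.64 without vehicle replicate 2, PTGER3 to 0.52 without vehicle replicate 3, and PTGER4 to between 0.60 and 1.53 without 1 vehicle array. These refits had no donor block and do not test the blocked calls. With all arrays of 1 donor number left out, only PTGER4 of these moved by over 1.5 times (1.44 without replicate 2). The calls of NT5E (adjusted p up to 0.21), VSIR (0.181), BMF (0.12), CYTH4 (0.109), PDGFA (0.175), SGK1 (0.133), PDE2A (0.14) and IL1RL1 (0.186) ended without any 1 of 5 of the 6 arrays compared, and that of PTPN6 (0.159) without any 1 of the 6.

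The comparison of the combination with vehicle asked what both agents changed together. It had 253 genes risen and 117 fallen, or 1331 and 1818 with the donor block. SHISA2, which encodes a membrane protein that holds back receptors of the Wnt and FGF pathways in the endoplasmic reticulum, rose by 8.53 on the log2 scale (SE 0.59, adjusted p = 3.25e-05), from 3.52 ± 0.27, under the background percentile, to 12.05 ± 0.80 (SD, n = 3). The size and rank of its rise are therefore uncertain, as they are for CEMIP, TKTL1, PLAT, GJA1 and SV2C and for the fall of NHSL2. CEMIP (7.40), TKTL1 (7.17), AKAP12 (6.34), PLAT (6.09), SIK1 (5.92), the dexamethasone-induced Ras protein gene RASD1 (5.71), THBD (5.55), CXCL5 (5.42), FGL2 (5.20), GJA1 (5.16) and SV2C (5.14) followed. Among the genes that passed without the block, the largest falls were those of urokinase PLAU (-2.70), the microRNA gene MIR146A (-2.63), CHST13 (-2.59), PDGFA (-2.54), CYTH4 (-2.53) and the xenobiotic-metabolizing CYP1A1 (-2.30). UMODL1 (-2.16), LOC100996740 (-2.15), NHSL2 (-2.10), GCSAML (-1.99), SASH3 (-1.98) and GLIS2 (-1.96) fell as well. All of these changed in 1 direction in 3 of 3 donor pairs. Other probe sets changed by much less for CEMIP (1.44), TKTL1 (2.16), SIK1 (0.05), CXCL5 (0.50 and 0.77), MIR146A (-0.02), CHST13 (-0.23) and NHSL2 (-0.09).

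Both pathway lists rose with the combination. Of 27 glucocorticoid receptor targets, 9 rose, 0 fell and 18 did not pass, and 17 rose when adjusted over the list alone (median 1.02, camera adjusted p = 7.94e-25, adjusted p = 0.00101 with an estimated correlation). SGK1 rose by 4.29, RGS2 by 4.21, CXCR4 by 3.01 (SE 0.17, 8.03-fold) and the phosphatase DUSP1 by 2.10. SGK1, RGS2 and CXCR4 had also risen with dmPGE2 alone. The 2 pathway lists share PER1, DUSP1 and RGS2, so their rises are not independent. Of 27 cAMP and CREB targets, 12 rose, 0 fell and 15 did not pass, and 20 rose when adjusted over the list alone (median 2.19, camera adjusted p = 1.13e-33, adjusted p = 0.00369 with an estimated correlation). CREM rose by 3.89, NR4A3 by 3.60, PDE4B by 3.04 and PDE4D by 2.74. The donor block called 22 glucocorticoid receptor targets and 23 cAMP and CREB targets higher, and 1 of the former lower.

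The immunoregulatory list was not called with the combination (camera adjusted p = 0.532). Of its 32 members 1 rose, 0 fell and 31 did not pass, against 3 risen and 1 fallen when adjusted over the list alone and 5 higher and 4 lower with the block. ARG2 rose by 1.53. With the block, CD274 was called 1.54 higher (blocked adjusted p = 0.00573, against SE 0.61 and adjusted p = 0.356 without the block), at 8.95 ± 0.44 against 7.41 ± 1.29 in vehicle (SD, n = 3). It was only 0.79 higher without vehicle replicate 3, which left donor 3 unmatched, and 0.96 higher without replicate 3 of all groups. These refits held no donor block and do not test the blocked call. The costimulatory ligand gene ICOSLG (1.66, blocked adjusted p = 4.3e-05) and NT5E (2.58, 0.000825) were also higher with the block, and the death ligand gene TNFSF10 was lower (log2 fold change -3.05, blocked adjusted p = 9.99e-05). Of 26 inflammatory cytokines and NF-kB targets, 0 passed, 4 were lower when adjusted over the list alone, and 3 were higher and 10 lower with the block (median -0.27, camera adjusted p = 0.0659). CXCL10 (-4.65, blocked adjusted p = 0.000233) and TRAF1 (-2.00, 0.000576) were among the lower ones.

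The stem cell list was not called with the combination. Of 25 stem cell genes, 0 rose and 2 fell, namely the transcription factor genes LMO2 (-1.20, SE 0.26, adjusted p = 0.0418) and ERG (-1.17, SE 0.25, 0.0394), with 23 not passed, 3 risen and 4 fallen when adjusted over the list alone, 6 higher and 5 lower with the block, and a camera adjusted p = 0.965. CIITA, the master regulator of MHC class II, fell by 1.39 on the log2 scale (adjusted p = 0.0295), as 1 of 13 measured members of its list, with 2 fallen when adjusted over the list alone and 2 lower with the block. This list was not called (camera adjusted p = 0.941), with a median of 0.09 and a mean of -0.02. MCL1 (1.30), BCL2L11 (2.31) and GADD45A (1.89) were the 3 of 23 apoptosis and survival genes that rose, against 5 risen and 1 fallen when adjusted over the list alone, and 6 higher and 2 lower with the block (camera adjusted p = 0.0659). The hormone precursor ADM (3.01) was the 1 of 18 heat shock and handling stress genes that rose, with 2 risen when adjusted over the list alone, and 4 higher and 2 lower with the block. This list's camera adjusted p = 0.0659, with blocked adjusted p = 0.0161, but blocked adjusted p = 0.115 with an estimated correlation. Homing, adhesion and migration genes had CXCR4 risen and ITGAL (-1.65) fallen, in the same numbers when adjusted over the list alone, and 3 higher and 3 lower with the block (camera adjusted p = 0.965). None of the 26 signalling components passed, against 4 higher and 5 lower with the block. With the block, NR3C1 (0.63, blocked adjusted p = 0.0272) and PTGER4 (1.14, 0.0108) were higher and HPGDS (-1.11, 0.00108) and ADCY7 (-1.12, 0.0047) lower, with 0.27 and -0.36 in the other probe sets of PTGER4 and ADCY7. Of the 47 named genes called with the combination, 35 stayed called without any 1 array and 12 also without any 1 donor number. ADCY7 went to -0.39 without combination replicate 1 and PTGER4 to 1.71 without vehicle replicate 2, in fits without the donor block that do not test the blocked calls. The calls of LMO2 (adjusted p up to 0.145), CIITA (0.109), KLF1 (0.157), LOC100996740 (0.138) and CYP1A1 (0.127) ended without any 1 of 5 of the 6 arrays compared, and that of ERG (0.152) without any 1 of the 6. The count of 370 genes became 208 and 230 without vehicle replicates 1 and 2, 233 and 198 without combination replicates 1 and 2, and 62 without replicate 2 of all groups.

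**Figure D2:**
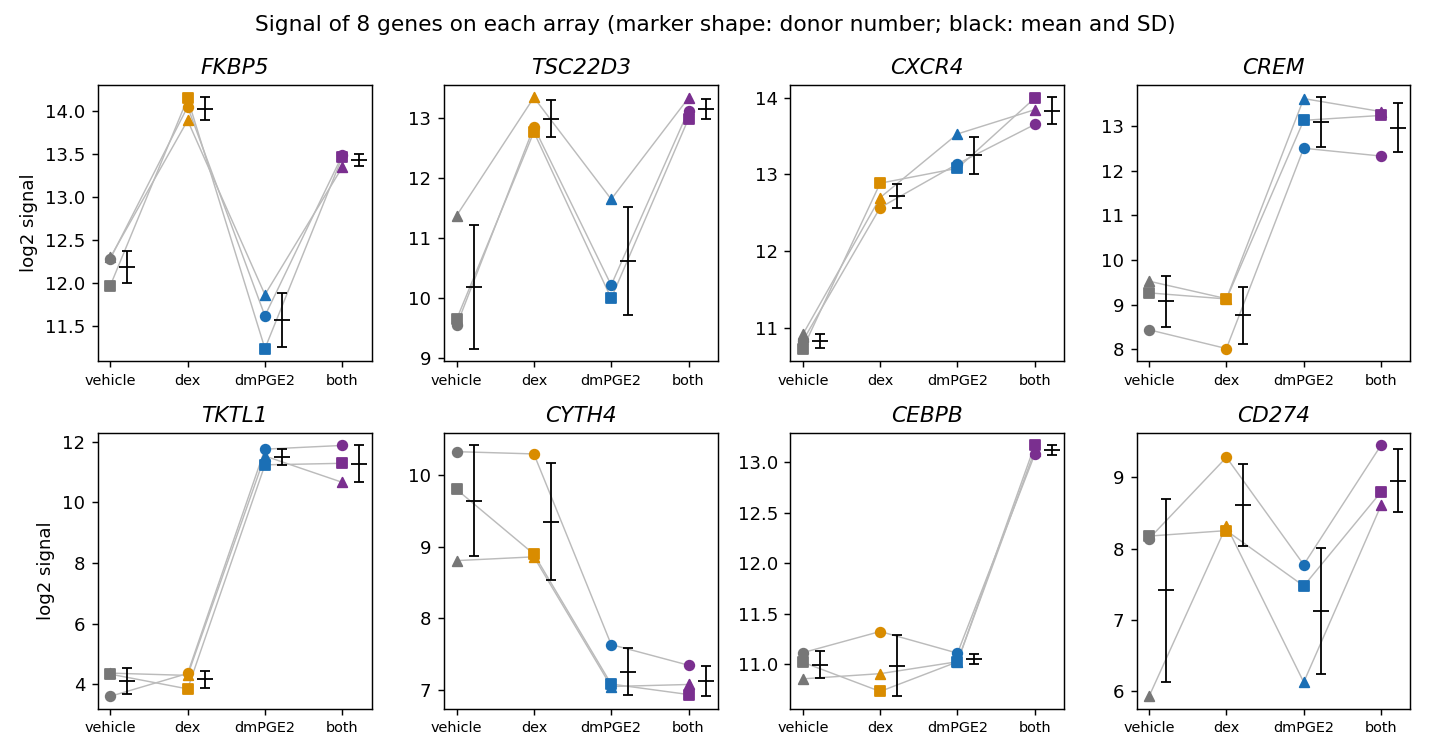
Log2 RMA signal of FKBP5, TSC22D3, CXCR4, CREM, TKTL1, CYTH4, CEBPB and CD274 in each of the 12 arrays, by treatment group, with marker shapes for the donor numbers and black marks for the mean and SD of n = 3 arrays. CEBPB lies near 11 in the first 3 groups and at 13.12 ± 0.05 in the combination.

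The lists of markers of other blood cells, which a CD34+ preparation might hold, were not called by camera with dmPGE2 or the combination. Of 18 T and NK cell markers, 12 B cell markers, 15 monocyte and dendritic cell markers and 12 granulocyte precursor markers, 0 passed in limma in either comparison, with 1 T and NK cell marker higher with dmPGE2 when adjusted over the list alone and 0 of the other 3 lists. Camera adjusted p-values with dmPGE2 were 0.338, 0.655, 0.655 and 0.928. With the block, 3 T and NK cell markers were higher and 0 lower in each comparison, the cytotoxic granule gene GZMB among them with dmPGE2 (1.98, blocked adjusted p = 0.000372), and directional fry called that list higher (blocked adjusted p = 0.0152 with dmPGE2 and 0.0107 with the combination). A shift of T and NK cell markers therefore stays open. The block called 1 B cell marker higher and 1 lower with dmPGE2 and 0 and 2 with the combination, 1 and 1 and then 1 and 0 monocyte and dendritic cell markers, and 1 and 0 and then 0 and 0 granulocyte precursor markers. Of 11 erythroid markers, 0 passed with dmPGE2 and 1 was lower when adjusted over the list alone, and 1 was higher and 2 lower with the block (camera adjusted p = 0.655), while with the combination the carbonic anhydrase CA1 rose by 1.94 (0.14 in its other probe set) and the erythroid transcription factor KLF1 fell by 1.09 on the log2 scale. THBS1 was the 1 of 11 megakaryocyte and platelet markers that rose in both comparisons, also when adjusted over the list alone (camera adjusted p = 0.449 with dmPGE2). With the block 2 were higher in both and 1 lower with the combination, and directional fry called the list higher with dmPGE2 (blocked adjusted p = 0.0288). IL1RL1, the receptor for interleukin-33, was the 1 of 9 mast cell and basophil markers that rose in both, by 2.64 and 3.52, also when adjusted over the list alone (camera adjusted p = 0.509 with dmPGE2), and with the block 2 were lower with dmPGE2 and 1 with the combination. The median, mean and camera direction did not have 1 sign in 4 lists with dexamethasone, 6 with dmPGE2 and 7 with the combination, among them the monocyte (median -0.07 and mean 0.03), megakaryocyte (-0.11 and 0.49) and mast cell markers (-0.07 and 0.14) with dmPGE2, and 0 of these lists were called by camera.

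The lists of general cell functions were not called by camera either. Of 28 cell cycle genes 0 passed with dmPGE2 or the combination, with 1 higher with dmPGE2 when adjusted over the list alone (camera adjusted p = 0.449). With the block 5 were higher and 1 lower with dmPGE2, and 5 and 2 with the combination. CDC6, which licenses replication origins, was 2.11 higher with dmPGE2 in the blocked fit (blocked adjusted p = 0.000399). Of 15 cholesterol synthesis genes 0 passed, with 1 higher when adjusted over the list alone (camera adjusted p = 0.706, median -0.10 and mean 0.11). With the block 2 were higher and 0 lower in each comparison, among them the sterol carrier STARD4 with dmPGE2 (1.84, blocked adjusted p = 0.000539). Of 20 ribosome biogenesis and MYC targets 0 passed over all genes or when adjusted over the list alone, and 1 was higher and 1 lower with the block in each comparison (camera adjusted p = 0.509 with dmPGE2). Of 27 type I interferon response genes 0 passed either way with dmPGE2 (camera adjusted p = 0.243), and 5 were higher and 2 lower with the block, among them ISG20 (2.45, blocked adjusted p = 2.78e-07) and MX2 (1.66, 0.000899). With the combination 0 passed either way, and 4 were higher and 5 lower with the block. Of 13 MHC class II presentation genes 0 passed with dmPGE2, with 1 lower when adjusted over the list alone, and 2 higher and 1 lower with the block (camera adjusted p = 0.444). CIITA was 1.03 lower (log2 fold change -1.03, blocked adjusted p = 0.00398).

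**Figure D3:**
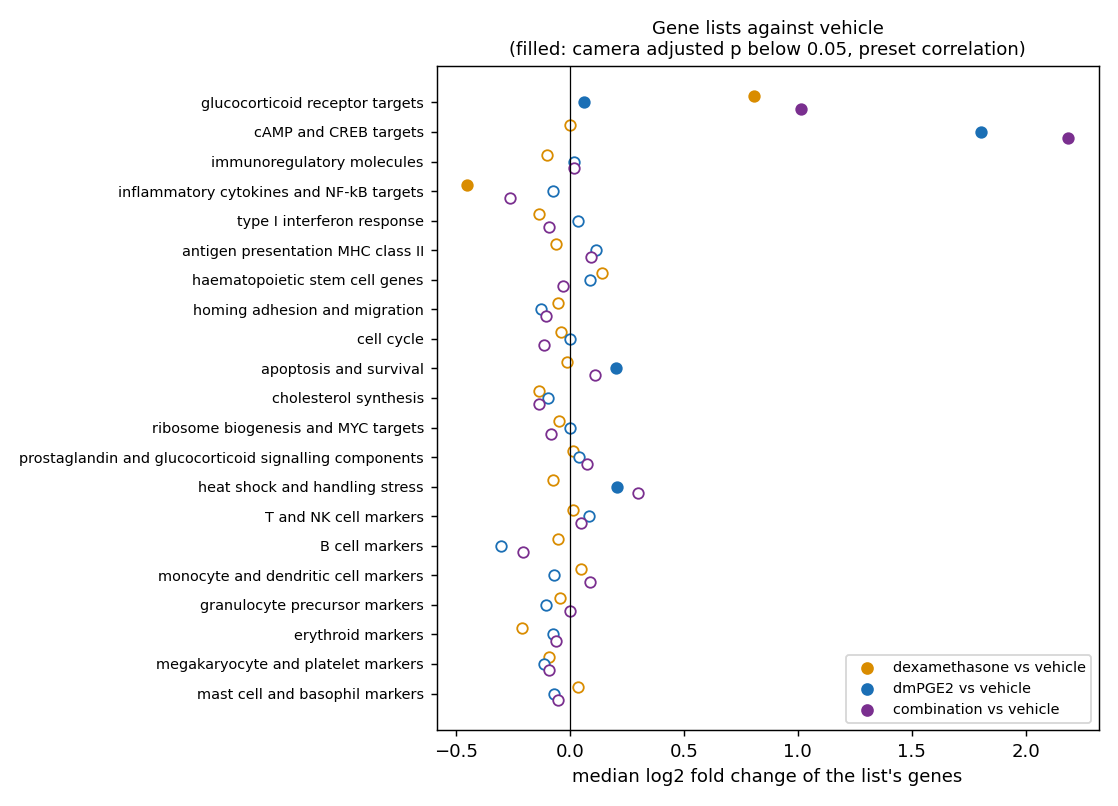
Median log2 fold change of the measured members of each of the 21 gene lists, for dexamethasone, dmPGE2 and the combination against vehicle, with filled markers for lists with a camera adjusted p below 0.05. The cAMP and CREB targets lie at 1.80 with dmPGE2 and 2.19 with the combination, and the glucocorticoid receptor targets at 0.81 with dexamethasone and 1.02 with the combination.

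The comparison of the combination with dexamethasone asked what dmPGE2 added to the glucocorticoid. CEMIP (7.53, SE 0.33), TKTL1 (7.10), AKAP12 (6.02), PLAT (5.69), SV2C (5.52) and BABAM2-AS1 (5.43) had the largest log2 differences upward among the genes that passed without the block, though the dexamethasone means of CEMIP, TKTL1, PLAT and SV2C lay under the background percentile and the other probe sets of CEMIP and TKTL1 were only 1.14 and 2.34 higher, and CREM was 4.20 higher (SE 0.42, 18.4-fold). Among the genes that passed without the block, UMODL1 (-2.27), CYTH4 (-2.23), the lymphoid GTPase gene GIMAP1 (-2.13), the haematopoietic nuclear protein HEMGN (-2.03), BMF (-1.98) and the erythroid cell expansion regulator RHEX (-1.84) had the largest falls. In all, 216 genes were higher and 67 lower, or 1122 and 1299 with the block, and 41 without replicate 2 of all groups. The count was 172, 154 and 142 without dexamethasone replicates 1, 2 and 3, and 161 and 169 without combination replicates 1 and 2, and the call of CYTH4 ended without any 1 array (adjusted p up to 0.122) and those of GIMAP1 (0.141) and HEMGN (0.151) without any 1 of 5 of the 6. Of 27 cAMP and CREB targets, 11 rose, 0 fell and 16 did not pass, with 19 risen when adjusted over the list alone and 23 higher with the block (camera adjusted p = 2.5e-35, adjusted p = 0.00627 with an estimated correlation). Of 27 glucocorticoid receptor targets 5 rose, 0 fell and 22 did not pass, with 9 risen and 1 fallen when adjusted over the list alone, and 13 higher and 2 lower with the block. Their camera adjusted p = 8e-06, but adjusted p = 0.0627 with an estimated correlation. CXCR4, 1 of these, was 1.11 higher than with dexamethasone alone (SE 0.17, adjusted p = 0.00861). Apoptosis and survival genes (2 risen, 0 fallen, 21 not passed, 4 risen when adjusted over the list alone, and 8 higher and 1 lower with the block) had a camera adjusted p = 0.00961, and adjusted p = 0.0989 with an estimated correlation. Heat shock and handling stress genes (1 risen, 0 fallen, 17 not passed, 2 risen when adjusted over the list alone, and 6 higher and 1 lower with the block) also had 0.00961, and adjusted p = 0.328 with an estimated correlation.

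The comparison of the combination with dmPGE2 asked what dexamethasone added to the prostaglandin. It called 7 genes, all higher. CEBPB (Entrez Gene 1051), a transcription factor of myeloid differentiation, rose by 2.06 (SE 0.17, 4.18-fold, adjusted p = 0.00113), from 11.05 ± 0.05 to 13.12 ± 0.05 (SD, n = 3). The cyclin gene CCNA1 rose by 3.87 (SE 0.32, 14.6-fold, 0.00113), FKBP5 by 1.86 (SE 0.18, 0.00363), the betaine transporter gene SLC6A12 by 1.60 (SE 0.15, 0.00289), the lymphoid transcription factor gene IKZF1 by 1.33 (SE 0.17, 0.0356), SERTM1 by 2.32 (SE 0.31, 0.0478) and SHISA2 by 4.27 (SE 0.59, 19.3-fold, 0.0485). All 7 were higher in 3 of 3 pairs. The means of SERTM1 and SLC6A12 with dmPGE2, 2.73 and 4.20, lay under the background percentile, so the size of their rise is uncertain. The donor block called 129 higher and 57 lower. Glucocorticoid receptor targets had 1 of 27 risen, 0 fallen and 26 not passed, with 13 risen when adjusted over the list alone (median 0.85, camera adjusted p = 1.74e-36, adjusted p = 0.000231 with an estimated correlation), and 12 were higher with the block. SLA (2.68, blocked adjusted p = 1.89e-05), TSC22D3 (2.54, 0.000317), ZBTB16 (2.22, 0.00105), PIK3IP1 (2.01, 8.66e-05) and the scavenger receptor CD163 (1.55, 0.0161) were among the latter.

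With the block, CD274 was also higher with the combination than with dmPGE2 alone, by 1.83 (SE 0.61 and adjusted p = 1 without the block, blocked adjusted p = 0.013, with 0.47 in its other probe set), as were VSIR by 1.13 (adjusted p = 0.0807, blocked adjusted p = 0.00168), the phosphodiesterase gene PDE2A by 2.40 (0.00187), CRYBG1 by 1.76 (5.87e-05), CCND3 by 1.47 (0.000281), AKR1C2 by 1.39 (0.000627) and AKR1C1 by 1.26 (0.00106). S1PR1 (-1.68, 0.00179), HMOX1 (-1.57, 0.000317), ERG (-1.06, 0.00242) and MMP9 (-0.97, 0.00349) were lower with the block. In fits without the block, the differences without combination replicate 1 were 0.72 for AKR1C1 and 0.90 for AKR1C2, and without dmPGE2 replicate 3 that of HMOX1 was -0.94. Camera called 3 further lists. The cAMP and CREB targets (median 0.14, camera adjusted p = 0.0436), the inflammatory cytokines and NF-kB targets (median -0.22, 0.00291) and the type I interferon response genes (median -0.19, 0.00233) each had 0 members called, 0 adjusted over the list alone, and adjusted p = 0.654 with an estimated correlation. With the block 2 of the first were higher and 1 lower, and 1 of the second was lower. CEBPB, CCNA1, FKBP5 and SLC6A12 stayed called without any 1 array, and none of the 7 stayed called without each donor number in turn. SHISA2 (adjusted p up to 0.262), IKZF1 (0.251) and SERTM1 (0.251) were lost without any 1 of 5 of the 6 arrays compared, and 4 genes were called without dmPGE2 replicate 1 or without combination replicate 2.

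The direct comparison of dexamethasone with dmPGE2 gave 64 genes higher with dexamethasone and 181 lower, or 991 and 1064 with the block. Among the genes that passed without the block, SIGLEC15 (3.43), MMP7 (3.38), PNMT (2.88), the kinase inhibitor PIK3IP1 (2.82), ZBTB16 (2.74) and LCN10 (2.62) were the most elevated in the dexamethasone arrays, and FKBP5 was 2.45 higher (SE 0.18, adjusted p = 6.12e-05). TKTL1 (-7.33, SE 0.32), CEMIP (-7.10), DUSP4 (-6.31), the activin subunit INHBA (-6.03), SV2C (-5.90) and GJA1 (-5.87) were the lowest relative to dmPGE2, though the dexamethasone means of TKTL1, CEMIP, SV2C and GJA1 lay under the background percentile and the other probe set of CEMIP had -0.85. VSIR was 1.41 higher with dexamethasone (SE 0.17, adjusted p = 0.00203) and MMP9 lower (-2.62, 5.91e-05), and TSC22D3, at 2.37 higher, passed only with the block (adjusted p = 0.0545, blocked adjusted p = 6.56e-05). Of 27 cAMP and CREB targets, 0 were higher, 9 lower and 18 not passed, with 16 lower when adjusted over the list alone (median -1.78, camera adjusted p = 1.56e-31, adjusted p = 0.00921 with an estimated correlation). The immunoregulatory molecules (1 higher and 1 lower of 32, and 1 and 2 when adjusted over the list alone) had a camera adjusted p = 0.0262, and adjusted p = 0.557 with an estimated correlation. For the inflammatory cytokines and NF-kB targets (0 and 1 of 26, and 0 and 2 when adjusted over the list alone) these were 0.0256 and, as adjusted p with an estimated correlation, 0.883. The type I interferon response genes (0 and 0 of 27, and 0 and 2 when adjusted over the list alone) had 0.00934 and 0.678, the apoptosis and survival genes (0 and 1 of 23, and 0 and 4 when adjusted over the list alone) 0.0047 and 0.0824, and the heat shock and handling stress genes (0 and 1 of 18, and 0 and 1 when adjusted over the list alone) 0.00813 and 0.308, in that order. The MHC class II presentation genes were called only with the block (camera adjusted p = 0.0885, blocked adjusted p = 0.0361), and not with an estimated correlation (blocked adjusted p = 0.5), with 0 of 13 members called, 0 adjusted over the list alone and 1 lower with the block. For the lists before it the block called 0 higher and 21 lower, 2 and 6, 1 and 5, 0 and 5, 0 and 5, and 1 and 6, in the order given. The count of 245 genes became 144 without dexamethasone replicate 3, 161 and 140 without dmPGE2 replicates 1 and 2, and 46 without replicate 2 of all groups, and the call of ZBTB16 ended without any 1 of 5 of the 6 arrays compared (adjusted p up to 0.175).

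The interaction asked whether the response to both agents differed from the sum of the responses to each on the log2 scale. In limma without the block 0 genes passed. An unadjusted p below 0.05 was found for 137 genes, against 824 with the block, both less than 0.05 of the 19740 genes. Without the block the donor differences stayed in the residual spread, so the 137 do not speak against changed genes. With the donor block 3 passed higher and 1 lower. CEBPB, at 10.99 ± 0.30 with dexamethasone and 11.05 ± 0.05 with dmPGE2 (SD, n = 3), exceeded the sum by 2.07 with both (SE 0.24, adjusted p = 0.0668, blocked adjusted p = 0.00317). SLC6A12 exceeded it by 1.53 (SE 0.21, 0.184, blocked adjusted p = 0.0126) and CRYBG1 by 1.51 (SE 0.93, 1, blocked adjusted p = 0.0205), or by 0.97 without dmPGE2 replicate 3. Each SE here is that of the fit without the block, not of the blocked test. S1PR1-DT, a transcript divergent to S1PR1, fell short of the sum (log2 difference -2.74, SE 0.59, adjusted p = 1, blocked adjusted p = 0.0126), and S1PR1 itself had -1.97 (blocked adjusted p = 0.0678). SERTM1 (2.07) and CXCR4 (-1.31) had the remaining smallest p and passed in neither fit. The vehicle, dexamethasone and dmPGE2 means of SERTM1 and of SLC6A12 lay under the background percentile, so the size of their interactions is uncertain. The interaction for CD274 was 0.62 (SE 0.87, adjusted p = 1, blocked adjusted p = 0.935), and between 0.12 and 1.37 when 1 array was left out. Among the lists, the stem cell genes had a median of -0.24 and a camera adjusted p = 0.0316, with 0 of 25 members called and 0 adjusted over the list alone, adjusted p = 0.818 with an estimated correlation, and adjusted p = 0.0502 with the block.

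The response to dmPGE2 was shared with and without dexamethasone. Of the 183 genes that rose with dmPGE2 alone and the 216 that were higher with the combination than with dexamethasone, 138 were the same genes, against 2.00 for independent lists, and 26 were shared among the 49 and 67 lower ones, against 0.166. Across the 19740 genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.825, Spearman rho = 0.619 and a covariance of 0.185. The response to dexamethasone with and without dmPGE2 shared 1 called gene, FKBP5, against 0.000709 for independent lists, with r = 0.332, rho = 0.130 and a covariance of 0.0195. With the block the shared genes numbered 788 higher and 724 lower for dmPGE2, against 65.9 and 82.4 for independent lists. For dexamethasone they numbered 35 higher and 7 lower, against 0.444 and 0.0404. Of the 68 higher and 14 lower genes with dexamethasone alone in that fit, 68 and 13 moved the same way with dmPGE2 present. Their median log2 fold changes were 1.26 and -1.06 alone, and 0.99 and -0.89 with dmPGE2. The effects of the 2 agents against vehicle shared 1 gene, CXCR4, against 0.0185 for independent lists. With the block they shared 16 higher and 4 lower genes, against 3.99 and 0.888. Of the 68 higher and 14 lower genes with dexamethasone in that fit, only 27 and 8 moved the same way with dmPGE2 alone. The median dmPGE2 log2 fold changes of the 68 and the 14 were -0.06 and -0.21. Across all genes, the fold changes of the 2 agents had r = 0.277, rho = 0.387 and the same sign in 66.1% of genes. Unchanged groups simulated against the same vehicle arrays gave r = 0.50 and 66.7%. The covariance was 0.0313 against a simulated 0.0150, a difference of 0.0163, and part of it may come from the shared vehicle arrays. In 20 further simulations of unchanged groups the agents shared 0 calls, with or without the block. These held no gene changed by 1 agent, so a part of the shared calls from the shared vehicle arrays stays open.

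**Figure D4:**
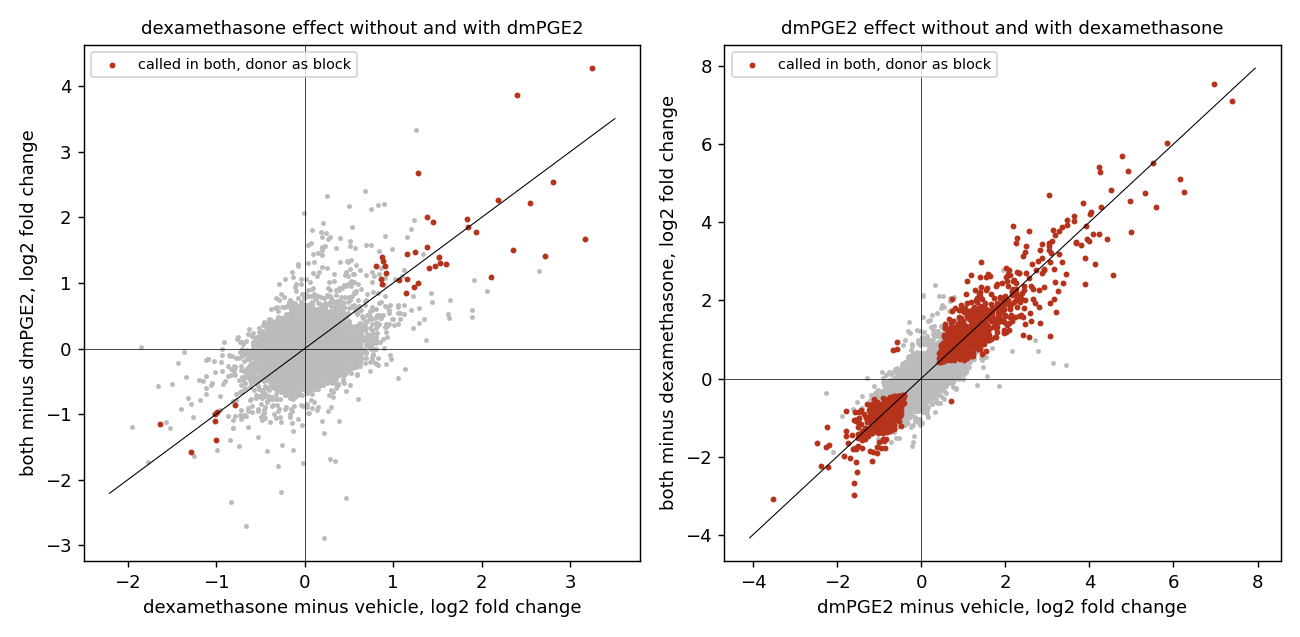
Log2 fold change of each of the 19740 genes, for dexamethasone without and with dmPGE2 in one panel and for dmPGE2 without and with dexamethasone in the other, with red for genes called in both with the donor block and a diagonal line of equal change. The dmPGE2 changes lie along the diagonal (r = 0.825), and the dexamethasone changes are smaller and more scattered (r = 0.332).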

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

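Of the tests in this part, those of background and of the top of the scale were chosen only after the result was seen. In the fit with the donor block, the response to both agents differed from the sum of the separate responses on the log2 scale for CEBPB (limma blocked adjusted p = 0.00317), CRYBG1 (0.0205), S1PR1-DT (0.0126) and SLC6A12 (0.0126), and none of the 4 passed without the block. Signal near background is argued against as the cause for CEBPB and CRYBG1, since their lowest group mean lay 4.22 above the 95th percentile of the bacterial controls. For S1PR1-DT and SLC6A12 it cannot be told apart from a joint response, because the higher of their lowest group means lay only 0.162 above that percentile, where a change cannot be measured. A signal limited by the top of the scale is argued against for S1PR1-DT, the only gene that it could have put under the sum, since its highest group mean lay 6.84 below the highest value on the arrays, while the distance of at least 1.83 over all 4 genes bears on none of the other 3. A joint action of both agents on CEBPB and CRYBG1, each measured by 1 probe set, may be weighed as a hypothesis, found and tested on the same arrays.

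Several named genes moved 1 way in all 3 donor pairs with an agent alone and the other way in all 3 when the other agent was present. The difference was tested as the interaction and passed for none of the following, with adjusted p = 1 without the block for each. With dexamethasone, PTGER4 had an interaction of 0.94 (-0.76 alone and 0.18 with dmPGE2, blocked adjusted p = 0.935). GIMAP8 had one of -0.93 (0.37 and -0.56, 0.935). TRAF3IP3 had one of 0.71 (-0.30 and 0.40, 0.935). With dmPGE2, AKR1C2 had an interaction of 0.52 (-0.07 alone and 0.44 with dexamethasone, 0.935). SLA had one of 1.39 (-0.66 and 0.73, 0.155). CD163 had one of 1.35 (-0.37 and 0.98, 0.935).

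Probe sets with no gene listed, which entered no comparison above, also held a signal. Of 11721 such probe sets, control probe sets left out, limma called 1 with dexamethasone, 49 with dmPGE2 and 78 with the combination against vehicle, or 22, 740 and 1059 with the block.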

How the results depend on the processing

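No test in this part was chosen after its result was seen, and all settings had been fixed before the data were examined. All counts are of genes or lists at a limma adjusted p below 0.05. The donor pairing mattered most. With the replicate block, the counts were 82 for dexamethasone and 2411 for dmPGE2 against vehicle, 3149 for the combination against vehicle, 2421 for the combination against dexamethasone, 186 for the combination against dmPGE2, 2055 for dexamethasone against dmPGE2 and 4 for the interaction. The main counts in that order were 2, 232, 370, 283, 7, 245 and 0, and every gene called without the block was called with it. Shared calls numbered 42 for dexamethasone with and without dmPGE2, 1512 for dmPGE2 with and without dexamethasone and 20 for both agents against vehicle with the block, against 1, 164 and 1. For the named genes the block added 82 calls and ended 0, and it ended the 1 list call of the interaction, leaving 0. It added a list call for the combination against vehicle (3 instead of 2) and for dexamethasone against dmPGE2 (7 instead of 6). It changed no other list call of camera.

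With only the arrays of the groups compared there were 0, 94, 113, 95, 0 and 157 genes in the 6 pairwise comparisons, in the order above, with fewer residual degrees of freedom by construction. The 0 genes of dexamethasone against vehicle and of the combination against dmPGE2 stood against 244 and 403 at an unadjusted p below 0.05 with all arrays. Both numbers are less than 0.05 of the 19740 genes. Without the block the donor differences stayed in the residual spread and raised the p-values. These numbers therefore show neither that further genes changed nor that none did. With the block, 1315 and 1449 genes had an unadjusted p below 0.05. With the mean over probe sets, 1 gene was called for dexamethasone against vehicle, 14 for the combination against dmPGE2 and 1 for the interaction, and 0 were shared by the dexamethasone effects. With each array centred on its median, 4 genes were called for the combination against dmPGE2 and 1 for the interaction. For these settings the cause was not tested. SHISA2 and SERTM1 were not called for the combination against dmPGE2 after quantile normalization again or centring.

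Arrays were left out only in fits without the donor block, so the blocked calls were not tested in this way. Leaving out 1 array, or all arrays of 1 donor number, gave 0 to 5 genes for dexamethasone and 40 to 173 for dmPGE2 against vehicle, 62 to 292 for the combination against vehicle, 41 to 192 for the combination against dexamethasone, 0 to 8 for the combination against dmPGE2, 46 to 173 for dexamethasone against dmPGE2 and 0 to 1 for the interaction. Leaving out 1 donor number gave 0 to 1 shared dexamethasone calls, 31 to 57 shared dmPGE2 calls and 0 calls shared by the agents. For each of the 3 comparisons with vehicle, the highest count came without vehicle replicate 3. The only direction that turned was that of NR3C1 with dexamethasone, which was called in no setting. Its main difference was 0.08, with -0.06 without vehicle replicate 2, -0.10 without replicate 2 of all groups and up to 0.23 without vehicle replicate 3. Of the other values for single named genes when arrays were left out, 1644 kept their side of the threshold, 392 lost the call and 26 gained it. Correlations across genes moved in 3 of 9 cases, all without 1 donor number.

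Camera with an estimated correlation called 1 list for dexamethasone and 1 for dmPGE2 against vehicle, 1 for the combination against dexamethasone, 1 against dmPGE2, 1 for dexamethasone against dmPGE2 and 0 for the interaction, where the preset correlation called 2, 4, 4, 4, 6 and 1. Directional fry called 1 list for dexamethasone and 2 for dmPGE2 against vehicle, 1 for the combination against dmPGE2, 1 for dexamethasone against dmPGE2 and 0 for the interaction. Mixed fry called 9 lists for the combination against vehicle, 1 for the combination against dmPGE2 and 0 for the interaction. The list call of the interaction also fell to 0 with genes above the 40th percentile and with quantile normalization again. Without 1 donor number the lists called were 2 to 4, 3 to 4, 2 to 4, 4 to 5, 2 to 4, 4 to 6 and 0 to 2, in the order of the comparisons above.

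In each pairwise comparison 3 arrays against 3 give 10 splits, too few for a share under 0.05. The real split gave 2, 232, 370, 283, 7 and 245 genes and the highest of the other splits 0 genes in each, so that 1 of 10 splits gave as many. Of the 10, 4 part all 3 donor pairs, the real split included, and the other 6 keep both arrays of 2 donors together. For the interaction the real count was 0, which any regrouping of the 12 arrays must reach, so the 100 regroupings say nothing about chance. Signal over background limits the folds of genes that are nearly silent in vehicle, and 20 of the 105 genes that rose at least 4-fold with dmPGE2 had a vehicle mean under the background percentile.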

Other observations

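Of the tests in this part, those of a hybridisation batch and of misread probe sets were chosen only after the result was seen, as were the gene families described first and the allowance for error in the test of RNA integrity. GIMAP genes, which encode GTPases of lymphocyte survival, were lower with dmPGE2 and with the combination than with vehicle in 7 of 7 measured members. In limma 0 of them passed without the donor block, against 5 with it, and their direction was the same under both rescalings. The values of these 5 with the combination were -1.66 for GIMAP1 (blocked adjusted p = 0.000213), -1.29 for GIMAP2 (0.000885), -1.94 for GIMAP6 (0.00028), -2.37 for GIMAP7 (8.19e-05) and -1.73 for GIMAP8 (0.000576, but -0.32 in its other probe set), with -1.29 for GIMAP7 without combination replicate 1. The cAMP-specific phosphodiesterases PDE4A (3.48 with dmPGE2, 3.88 with the combination), PDE4B and PDE4D rose in both, as 3 of 3 measured members, though the 4 other probe sets of PDE4A lay between -0.23 and 0.62 with dmPGE2 and between -0.07 and 0.98 with the combination. Of all 22 measured phosphodiesterases 4 rose in each comparison, while with the block 6 were higher with dmPGE2 and 7 higher and 1 lower with the combination. The fourth was PDE2A, at 2.18 with dmPGE2 (SE 0.41, adjusted p = 0.029, a call that ended without any 1 of 5 of the 6 arrays) and 4.58 with the combination (SE 0.41, adjusted p = 0.000193).

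CXC chemokines moved apart. Of 14 measured, 3 rose with dmPGE2, namely CXCL5, CXCL6 (4.14, SE 0.67, adjusted p = 0.0113) and CXCL14 (2.25, SE 0.24, adjusted p = 0.000913, from a vehicle mean under background), while with the block 6 were higher and 2 lower, CXCL10 among the latter. The neutrophil attractant CXCL6 was 2.67 higher with the combination and passed only with the block (blocked adjusted p = 0.000152). Of 4 measured AKR1C genes, 3 were called higher with dexamethasone in the blocked fit.

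Arrays of 1 donor number deviated together, with 55.8% of the variance between numbers against 31.5% between groups. A difference in the arrays' distributions is argued against, since after quantile normalization again the shares were 55.5% and 31.8%. RNA integrity stays open. The largest difference between donor numbers in the 3' minus 5' signal of ACTB and GAPDH was 0.445 on the log2 scale, under the bound of 0.5 but by less than its error (SE 0.160). The level itself was high for ACTB, with donor-number means of 4.12, 4.56 and 4.46, and lower for GAPDH, with 0.18, 0.57 and 0.20. What this 3' excess means for other probe sets was not tested. A hybridisation batch cannot be told apart from the donors, because 95.1% of the variance of the spiked-in hybridisation controls, which hold no donor RNA, lay between donor numbers and 1.89% between groups, so part of the donor effect may be technical, and differences between donors in biology stay open as untested.

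Of the genes that rose with dmPGE2, 105 did so at least 4-fold. A single misread probe set per gene is argued against for the 62 of them with other probe sets, taken as a set, since 93.2% of those other probe sets were higher too, against 44.5% for the remaining genes. It is not settled for each gene, as SIK1 and PDE4A had other probe sets that were not higher. The other probe sets had a median log2 change of 1.53, against 3.04 for the 105 genes. For 43 genes with 1 probe set a misread probe set stays open, as no second probe set exists. Contaminating stromal or endothelial cells, which the CD34 selection need not remove where they carry CD34, are argued against, since the upper quartile of the change of 31 of their markers was 0.0360 (median -0.11, 0 called by limma, median level 5.74 in the dmPGE2 arrays, 9.71 for SPARC and 8.70 for EGFL7 at the top, 10 markers under background in vehicle and 1 also in a fixed list). For the 62 genes as a set, a response of the cells to dmPGE2 may be put forward as a hypothesis.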
